A study of Homo sapiens with 6 samples.

How the data were processed

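Human bone marrow mesenchymal stromal cells of 3 healthy donors were expanded in parallel at 5% and at 20% oxygen, which gave 6 arrays, 3 in each of 2 groups. Per the labels' protocols, cells grew in alpha medium with 10% serum at 37 °C, either in a conventional incubator with 5% carbon dioxide in air, given there as 19.95% oxygen, or in a workstation with 5% carbon dioxide, 5% oxygen and 90% nitrogen. Cultures at passage 3 were collected at 70 to 80% confluence. Total RNA was extracted on columns, 250 ng was amplified with the Affymetrix 3' IVT Express chemistry into biotin-labelled cRNA, and 15 µg of cRNA was fragmented, per the labels' protocols. Since the priming is from the 3' end, probe sets far from the 3' end of a transcript read degraded RNA less well.

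The deposited values are linear intensities, 1 per probe set and array, for 54675 probe sets. The software, the background correction and the way the authors summarised probes into probe sets are not given in the sources used here. The values themselves show that each array was scaled, since the mean after trimming 2% at each end is 500 on every array. Array medians differed by 0.0828 on the log2 scale, under the limit of 0.1 set before the data were examined, so the deposited scaling was kept. Scaling to a common mean removes any difference in total RNA output between the groups.

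Probe sets were named from the platform annotation of 2016, in which 41097 had 1 gene symbol, 1801 had several and 11777 had none, and 41043 were matched by gene identifier to current symbols. The 62 control probe sets, and 59 probe sets of sex-linked genes that could identify a donor, were left out of all gene tests. For each gene the probe set with the highest mean over all arrays was used, which left 19740 genes, of which 10511 had several probe sets. Differences named in the text are those of that probe set, and further probe sets of a gene can differ from it in size or sign. No filter on dim genes was applied. A gene is called near background, or dim, where its mean lies below the 40th percentile, 57.7 intensity units. CA9 and BMI1, genes fixed in advance for reporting, had no probe set of their own among those used.

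Differences were computed on log2(intensity + 16) and tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The sources used here do not state the authors' test, so the fit without a block was the one reported first, as fixed before the data were examined. The donor numbers in the labels pair the arrays, because arrays with the same number came from the same donor. As a check, the deviations of the 2 arrays of a donor from their group means correlated across genes with r = 0.227, 0.158 and 0.135 in donors 1, 2 and 3, against -0.219 to 0.049 for arrays of different donors. The fit with the donor as a block was set beside the fit without it. Standard errors of single genes come from the fit without the block unless stated, and so include differences in level between donors. With 3 arrays in each group, an exact permutation of a single value cannot give a p below 0.1, and an exact sign flip over 3 pairs cannot give one below 0.25.

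A total of 29 gene lists, fixed before the data were examined, covered hypoxia, metabolism, proliferation, stress, stromal identity, matrix, differentiation, secreted factors and markers of other cell types. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists. Camera compares the genes of a list with all other genes. With an estimated correlation no list passed, and with fry, which tests whether the genes of a list move on balance one way, the glycolysis and stromal surface marker lists passed. The estimate was 0.082 for glycolysis, 0.148 for hypoxia-inducible factor targets outside glycolysis, 0.545 for immediate early genes and 0.932 for mitosis. It was below the preset for stromal surface markers (-0.027) and growth factors (-0.013). A correlation above the preset therefore does not account for the lost calls of those lists. Adjustment over the genes of a list alone is named where it was used. List medians were also set against 10000 random lists matched on mean expression in 20 bins.

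The genes named in the text followed a rule fixed before the data were examined. It took up to 12 genes per direction past the threshold with the same sign in all donors, filled to 8 per direction in order of p in the fit with the donor as a block where fewer passed. It also took up to 4 genes of every list with the smallest p in that fit, and a fixed set of hypoxia, senescence and stromal genes whatever their result. Genes outside the rule are said to be chosen after their values were seen.

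The test was checked on 20 simulated data sets of 19740 genes for the comparison of 5% against 20% oxygen. They had the real means, spreads as moderated by limma, independent errors, differences between donors and 200 changed genes. The donor differences were set low, since the full error variance was subtracted although each donor mean rests on 2 arrays. Shares without the block therefore rest on donor differences that are probably weaker than the real ones. Changes of 1, 2 and 3 log2 units were about equally common. Without the block, 6.87% of genes changed by 1 log2 unit were recovered at the adjusted threshold, 76.4% of those changed by 2 and 95.6% of those changed by 3. With the donor as a block the shares were 7.69%, 91.4% and 98.9%. Many large changes ease the adjusted threshold, so these shares hold for that mix and need not hold in the real data. A simulated shift of 0.5 in the glycolysis genes was called by camera in 100% of the simulations, without correlation between genes.

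Alternatives fixed in advance were a donor block (fixed or random), quantile normalization, centring of each array on its median, removal of dim genes, an intensity trend or a robust prior in eBayes, the mean of all probe sets of a gene, preference for probe sets not shared between genes, every probe set on its own, pseudocounts of 1 and 64 for the count of genes, an estimated correlation, fry, and leaving out each donor and each array. Several were added after seeing the data. These were the 18S ribosomal RNA signal as a covariate (within donors too for the means of the 2 hypoxia lists), leaving out the 5% oxygen arrays of donors 1 and 2, the 2 pseudocounts for all other results, and splits of the arrays within donors in the fit with the donor as a block. The counts adjusted over the glycolysis and hypoxia-inducible factor lists alone were also added then.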

Results

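Transcript levels were measured in human bone marrow mesenchymal stromal cells, the adherent fibroblast-like cells of marrow that are expanded in culture. Cells from each of 3 healthy donors were grown side by side at 2 oxygen levels. One culture of each donor was kept at 5% oxygen and the other in a conventional incubator, which the labels give as 20% oxygen and the growth protocol as 19.95%. All cultures were at passage 3 and were collected at 70 to 80% confluence, so each group held 3 arrays and each donor contributed 1 array to each group. Array medians ran from 55.9 to 59.2 intensity units and the brightest probe sets from 40335 to 45255. The number of arrays limits the precision, and differences are given on the log2(intensity + 16) scale, as 5% minus 20% oxygen, which understates the change of dim genes.

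The comparison asked which transcripts differ between cells expanded at 5% and at 20% oxygen. Genes of glycolysis and targets of the hypoxia-inducible factors, the transcription factors stabilised at low oxygen, stood higher at 5% oxygen as groups. The mean difference was 0.593 over 21 glycolysis genes and 0.543 over 34 targets outside glycolysis, and 19 and 30 of these genes were higher. Neither list passed in the test with an estimated correlation (adjusted p = 0.126 and 0.218), and the second list had a mean of only 0.11 in donor 2 and did not pass with fry (adjusted p = 0.108). No single gene of the 19740 tested passed an adjusted p of 0.05 in limma, with or without the donor as a block. The smallest adjusted p was 0.355 without the block and 0.707 with it. At an unadjusted p under 0.05 there were 1193 genes, 513 higher and 680 lower, where 987 would be expected by chance if p values were spread evenly. In the simulated data, where donor differences were set low, 3.37% of unchanged genes had such a p without the block and 4.97% with it. The 9 other splits of the 6 arrays into groups of 3 gave 631 to 1524. With the donor as a block there were 1379 such genes, and the 3 other splits that exchange arrays only within donors gave 704 to 1072. With 4 such splits the real one can be highest by chance in 1 of 4 cases, so they do not decide. Among all genes, 6111, or 31%, differed in the same direction in all 3 donors, where independent signs give 25%.

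Glycolysis genes differed by similar amounts in the 3 donors, with list means of 0.62, 0.61 and 0.56 in donors 1, 2 and 3. Of the 21 measured genes, 17 were higher at 5% oxygen in every donor, and 10 passed when adjusted over the list alone, all of them higher, against 0 when adjusted over all genes. PDK1, the kinase that holds pyruvate back from the mitochondrial citric acid cycle, stood at 1980 ± 217 intensity units at 5% oxygen and 784 ± 138 at 20% (SD, n = 3), a difference of 1.33 ± 0.20 (SE). ALDOC, an aldolase isoform, differed by 1.24, PFKFB4, a regulator of phosphofructokinase, by 1.07, PFKL, the liver-type phosphofructokinase, by 0.78 and PGK1, phosphoglycerate kinase, by 0.54. The other 5 genes past the threshold were HK2, PFKFB3, PKM, ALDOA and TPI1, with differences from 0.52 to 1.10. HK2, PFKFB3, PKM, ALDOA and TPI1 were named after their values were seen. Second probe sets of HK2 and PFKFB4 differed by -0.15 and -0.04. Further probe sets of PDK1, PFKL and PKM differed by as little as 0.51, 0.31 and 0.12, while those of PGK1 ran up to 0.84. LDHA, lactate dehydrogenase A, and SLC2A1, the glucose transporter GLUT1, did not pass, with differences of 0.31 and 0.29 that were positive in 3 of 3 donors.

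The camera test of the glycolysis list against all other genes gave an adjusted p of 2.35e-14 with the preset correlation. This call was lost with an estimated correlation (adjusted p = 0.126), while the fry test of a shift of the list itself gave an adjusted p of 0.0137. With the donor as a block, 8 of the 21 genes passed over the list alone, as PGK1 and TPI1 had adjusted p values of 0.0609 and 0.0667. The count of 10 was lower with arrays left out, where the list mean stayed at 0.568 to 0.631. Without donor 1, 2 or 3 it was 0, 0 and 1, without the 5% oxygen array of donor 1, 2 or 3 it was 2, 2 and 5, and without the 20% oxygen array of donor 1, 2 or 3 it was 2, 1 and 9. It was also 5 with the mean of all probe sets, and 0 with the signal of 18S ribosomal RNA as a covariate or without the 5% oxygen arrays of donors 1 and 2, where that signal was highest, both chosen after seeing the data.

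Among the 34 targets of hypoxia-inducible factors outside glycolysis, 20 were higher in all 3 donors and 7 passed when adjusted over the list alone, against 0 over all genes. AK4, a mitochondrial adenylate kinase, stood at 2780 ± 306 intensity units at 5% oxygen and 452 ± 352 at 20% (SD, n = 3), a difference of 2.98 ± 0.69 (SE). BNIP3 and BNIP3L, which mark mitochondria for autophagy, differed by 1.28 ± 0.22 and 1.10 ± 0.28 (SE). ANGPTL4, a secreted inhibitor of lipoprotein lipase, differed by 1.28 from a level near background at 20% oxygen, and P4HA1, a collagen prolyl hydroxylase subunit, by 0.84, although a second P4HA1 probe set differed by -0.21. FAM162A and ZNF395, named after their values were seen, completed the 7 with differences of 0.88 and 0.93, and the 5 probe sets of FAM162A ran from -0.02 to 0.92. Further probe sets of AK4 differed by as little as 1.72.

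Other targets of the same list did not pass. ANKRD37 differed by 1.23, with -0.03 in donor 2, and ADM, the vasodilator peptide adrenomedullin, by 0.81 with the same direction in 3 donors. A second ANKRD37 probe set differed by 0.28. VEGFA, the vascular growth factor, differed by 0.24 and NDRG1 by 0.05, both with a negative difference in donor 2. LOX, which crosslinks collagen, differed by 0.30 and EGLN3, an oxygen-sensing prolyl hydroxylase read near background, by 0.44. The list means were 0.72, 0.11 and 0.80 in donors 1, 2 and 3. Camera gave an adjusted p of 5.3e-13, which was lost with an estimated correlation (adjusted p = 0.218) and with fry (adjusted p = 0.108). The count of 7 fell to 0 without donor 1, 2 or 3, without the 5% oxygen array of donor 1 or 2, or without the 20% oxygen array of donor 3, was 3 without the 5% oxygen array of donor 3, and was 8 without the 20% oxygen array of donor 1 or of donor 2. The list mean ran from 0.409 to 0.76 in these fits. The count was also 0 with the 18S covariate, without the 5% oxygen arrays of donors 1 and 2, and at a pseudocount of 1, where the smallest adjusted p over the list was 0.0524.

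**Figure D1:**
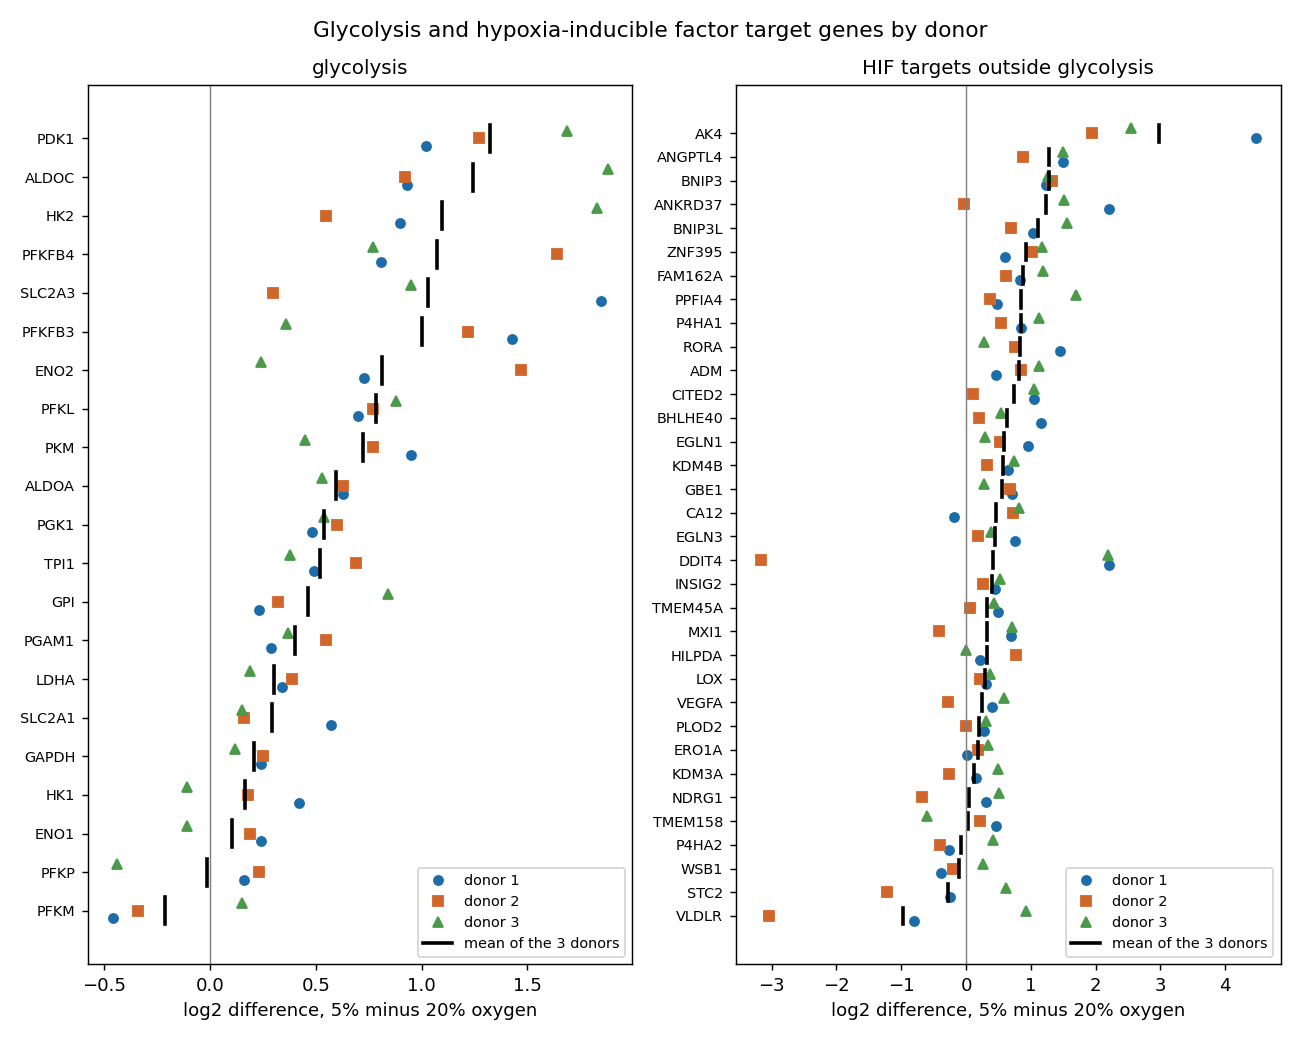
Difference in log2(intensity + 16) between 5% and 20% oxygen for each measured gene of the glycolysis list and of the list of hypoxia-inducible factor targets outside glycolysis, with 1 point per donor and a bar at the mean of the 3 donors. In the glycolysis list 17 of 21 genes lie above 0 in every donor and in the other list 20 of 34 do, and AK4 has the highest mean, 2.98.

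Genes of the hypoxia-inducible factors and VHL were fixed in advance for reporting. HIF1A differed by 0.31, positive in 3 of 3 donors, and EPAS1, which encodes HIF-2α, by -0.11, with further EPAS1 probe sets up to 0.92. HIF3A, which was near background, differed by 0.36, and VHL, the ubiquitin ligase subunit that marks hypoxia-inducible factors for degradation, by -0.13, with a second probe set at 0.46. None of the 4 passed, and the probe sets of EPAS1, HIF3A and VHL disagreed in sign. The long noncoding transcript MIR210HG, the host of a microRNA induced by hypoxia, differed by 3.14 ± 0.46 (SE) and stood at 348 ± 44.3 intensity units at 5% oxygen and 31.4 ± 30.5 at 20% (SD, n = 3). Its mean at 20% oxygen lay below the near-background level of 57.7, so the size of its difference depends on the pseudocount, from 2.15 at 64 to 3.98 at 1. Its adjusted p over all genes was 0.617.

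Surface markers of stromal cells were higher as a list, by a mean of 0.284 over 25 genes, of which 18 were higher. The list means were 0.18, 0.28 and 0.39 in donors 1, 2 and 3. PDGFRA, a growth factor receptor, differed by 0.97 ± 0.24 (SE) and was higher in 3 of 3 donors, but a second probe set differed by -0.19. CD9, a tetraspanin, differed by 1.16, with further probe sets down to 0, and PDGFRB by 0.94. The 3 markers that define these cells by convention, NT5E (CD73), THY1 (CD90) and ENG (CD105), differed by 0.35, 0.44 and 0.45, each positive in 3 donors. A further NT5E probe set differed by -0.31, and a second ENG probe set by 1.70. No gene of this list passed when adjusted over the list alone. Camera gave an adjusted p of 9.79e-05 and fry 0.0409. With an estimated correlation the list did not pass (adjusted p = 0.126), nor with fry and the donor as a block (adjusted p = 0.201). The estimate was -0.027, below the preset, so that loss does not show correlated genes.

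Matrix genes were also shifted upward by camera's test. The 48 collagens and matrix genes had a mean difference of 0.217 (adjusted p = 5.09e-04, and adjusted p = 0.666 with an estimated correlation), with 0.33, -0.07 and 0.39 in donors 1, 2 and 3. COL14A1, a collagen of fibril surfaces, differed by 1.80 ± 1.16 (SE), or ± 0.33 with the donor as a block, and was higher in 3 of 3 donors. The 22 genes of collagen modification and crosslinking had a mean of 0.166 (adjusted p = 0.00525, and adjusted p = 0.666 with an estimated correlation), with PLOD1, a lysyl hydroxylase, at 0.74 and LOXL1, a lysyl oxidase, at 0.64, while LOXL3 was lower in 3 of 3 donors, by -0.48. The means of that list were 0.23, -0.09 and 0.36 in donors 1, 2 and 3. Of its genes, P4HA1, P4HA2, PLOD2 and LOX were also counted among the hypoxia-inducible factor targets. No gene of either list passed over its list alone. Both calls ended without donor 3 (means 0.133 and 0.069) and without the 20% oxygen array of donor 3 (0.088 and 0.109). The call for collagen modification also ended without donor 1 (0.136) and without the 5% oxygen array of donor 3 (0.126). Quantile normalization ended the call for collagens and matrix (adjusted p = 0.171), and preferring probe sets specific to 1 gene ended that for collagen modification (adjusted p = 0.0721). With the signal of 18S ribosomal RNA as a covariate, an alternative chosen after seeing the data, the mean of collagens and matrix was 0.07 (adjusted p = 0.507), and it did not pass without the 5% oxygen arrays of donors 1 and 2 (0.128, adjusted p = 0.0606).

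Genes of mitosis had a mean difference of -0.516, and all 38 measured members had a negative difference. The direction was not shared by the donors, whose list means were -0.55, 0.49 and -1.49. MKI67, which encodes the proliferation antigen Ki-67, differed by -0.70 ± 0.52 (SE), AURKB, a mitotic kinase, by -0.75 and CCNB2, a cyclin, by -0.74. A further CCNB2 probe set differed by 0.02, and no member passed over the list alone. Camera gave an adjusted p of 5.37e-06, lost with an estimated correlation of 0.932 (adjusted p = 0.699), far above the preset of 0.01. The mean was -0.03 without donor 3 and -0.081 without the 20% oxygen array of donor 3, and neither value passed. Without donor 2 it was -1.018. The 32 DNA replication genes had a mean of -0.196 and the 32 DNA repair genes of -0.125, and neither list passed (adjusted p = 0.132 and 0.229). Without donor 2 their means were -0.66 and -0.343 and both passed, as both did without the 20% oxygen array of donor 2 (-0.557 and -0.281). DNA replication also passed without the 5% oxygen array of donor 2 (-0.299). Its mean turned to 0.117 without donor 3, 0.109 without the 20% oxygen array of donor 3 and 0.113 with the 18S ribosomal RNA covariate, while DNA repair fell to -0.008, -0.015 and 0.026, and none of these passed.

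The list of genes of the unfolded protein response and amino acid stress was lower, by a mean of -0.481 over 31 genes, of which 26 were lower and 7 were lower in all 3 donors. SHMT2, a mitochondrial enzyme of serine and glycine metabolism, differed by -0.84 ± 0.29 (SE), while ATF3, a stress-induced transcription factor of the list, was higher in 3 of 3 donors, by 1.95. A further ATF3 probe set differed by only 0.05. ATF3 turned to -2.04 with the 18S covariate and to -0.99 without the 5% oxygen arrays of donors 1 and 2. The shift lay in donor 2, with list means of -0.13, -1.37 and 0.06 in donors 1, 2 and 3. Camera gave an adjusted p of 0.00525, lost with an estimated correlation (adjusted p = 0.694). Without donor 2 the mean was -0.038 and without the 20% oxygen array of donor 2 it was -0.048, and neither passed. The call also ended when probe sets specific to 1 gene were preferred (adjusted p = 0.0806), with the 18S covariate (-0.997, adjusted p = 0.0919) and without the 5% oxygen arrays of donors 1 and 2 (-0.519, adjusted p = 0.447).

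Immediate early genes, which are transcribed within minutes of a stimulus, had a mean difference of 1.05 over 21 genes, of which 18 were higher and 13 were higher in all 3 donors. DUSP6, a phosphatase of the kinase ERK, differed by 1.06 ± 0.19 (SE) and was the 1 gene of the list past the threshold over the list alone, but not with the donor as a block (adjusted p = 0.0667). FOS and EGR1 differed by 2.37 ± 1.63 and 1.38 ± 0.76 (SE) and did not pass. Both were higher in 3 of 3 donors. With the donor as a block their SE was 0.59 and 0.33, and neither passed over the list alone. The list means were 2.10, 0.45 and 0.60 in donors 1, 2 and 3. Camera gave an adjusted p of 3.83e-06, lost with an estimated correlation of 0.545 (adjusted p = 0.666), far above the preset of 0.01. The probe sets for 18S ribosomal RNA were brighter at 5% oxygen by 3.94, 2.30 and 0.88 log2 units in donors 1, 2 and 3. With the 18S signal as a covariate, an alternative chosen after seeing the data, the list mean was -0.67, and without the 5% oxygen arrays of donors 1 and 2 it was -0.165. The value of -0.67 was the lowest of all settings, and the highest was 1.661, without the 5% oxygen array of donor 3.

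A further 5 lists were shifted upward by camera, with means from 0.056 to 0.307, and each lost its call with an estimated correlation. For growth factors the estimate was -0.013, below the preset, so that loss does not show correlated genes. Cholesterol synthesis had a mean of 0.307 (adjusted p = 0.00525, and adjusted p = 0.666 with an estimated correlation), with MSMO1, DHCR7 and IDI1, enzymes of sterol and isoprenoid synthesis, at 0.84, 0.81 and 0.61, although another IDI1 probe set differed by -0.29. Smooth muscle and myofibroblast genes had a mean of 0.26 (adjusted p = 0.0155, and adjusted p = 0.694 with an estimated correlation), with MYOCD, a transcriptional coactivator of smooth muscle genes, at 1.47 and ACTC1, cardiac actin, at 1.37, while SYNM, an intermediate filament gene, was lower in 3 of 3 donors, by -0.79. Secreted growth factors had a mean of 0.205 (adjusted p = 0.0297, and adjusted p = 0.303 with an estimated correlation), with HGF, hepatocyte growth factor, at 1.58 ± 0.40 (SE) and STC1, stanniocalcin 1, at 0.79, although another STC1 probe set differed by -0.34. Inflammatory cytokines and chemokines had a mean of 0.206 (adjusted p = 0.044, and adjusted p = 0.666 with an estimated correlation), with PTGES and PTGS2, enzymes of prostaglandin synthesis, at 1.03 and 1.59. The cytokine list differed by 0.58, -0.26 and 0.30 in donors 1, 2 and 3, and PTGS2 by -0.16 in donor 2. Subunits of oxidative phosphorylation had a mean of 0.056 (adjusted p = 0.044, adjusted p = 0.677 with an estimated correlation and 0.0917 with the donor as a block). Their median lay at percentile 87.2 among random lists matched on expression, against 98.3 to 100 for the other lists of this paragraph. A lift of bright probe sets therefore stays open for the oxidative phosphorylation list. NDUFA10 differed by -0.57, COX4I1 by 0.18 and its isoform COX4I2 by -0.17, and none passed. Further probe sets ran up to 0.07 in NDUFA10 and down to -0.63 in COX4I1.

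These 5 calls were lost in several fits with fewer arrays, at times with the mean unchanged or higher, so a lost call does not show that the array left out carried the shift. Without donor 3 none of them passed, at means of 0.192, 0.116, 0.189, 0.16 and 0.06 in the same order, nor did they without the 20% oxygen array of donor 3, at 0.183, 0.045, 0.162, 0.091 and 0.07. Without donor 1 the growth factor, cytokine and oxidative phosphorylation lists did not pass, at 0.141, 0.02 and 0.022. Without the 5% oxygen array of donor 1 the cholesterol, growth factor and cytokine lists did not pass (0.184, 0.147 and 0.1). Without that of donor 2 the smooth muscle and oxidative phosphorylation lists did not (0.107, and an unchanged 0.056). Without the 5% oxygen array of donor 3 the cholesterol, growth factor, cytokine and oxidative phosphorylation lists did not pass (0.316, 0.232, 0.276 and 0.046). Without the 20% oxygen array of donor 1 the growth factor, cytokine and oxidative phosphorylation lists did not pass (0.198, 0.126 and 0.012), and without that of donor 2 the cholesterol list did not (0.244). Quantile normalization ended the calls for smooth muscle (adjusted p = 0.141), growth factor (adjusted p = 0.0801) and oxidative phosphorylation genes (adjusted p = 0.401), and centring each array on its median ended that for oxidative phosphorylation (adjusted p = 0.0503). With the mean of all probe sets the smooth muscle, cytokine and oxidative phosphorylation lists did not pass (adjusted p = 0.133, 0.115 and 0.293). With probe sets specific to 1 gene preferred only cholesterol synthesis passed. Smooth muscle, growth factor and cytokine genes then had adjusted p values of 0.0671, 0.0671 and 0.125, and oxidative phosphorylation turned to -0.021. With the 18S covariate only cholesterol synthesis passed as well, while smooth muscle and cytokine genes turned to -0.161 and -0.191 and growth factor and oxidative phosphorylation genes fell to 0.094 and 0.013. Without the 5% oxygen arrays of donors 1 and 2 the 4 lists other than cholesterol synthesis did not pass either, at 0.117, 0.151, 0.068 and 0.077.

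**Figure D2:**
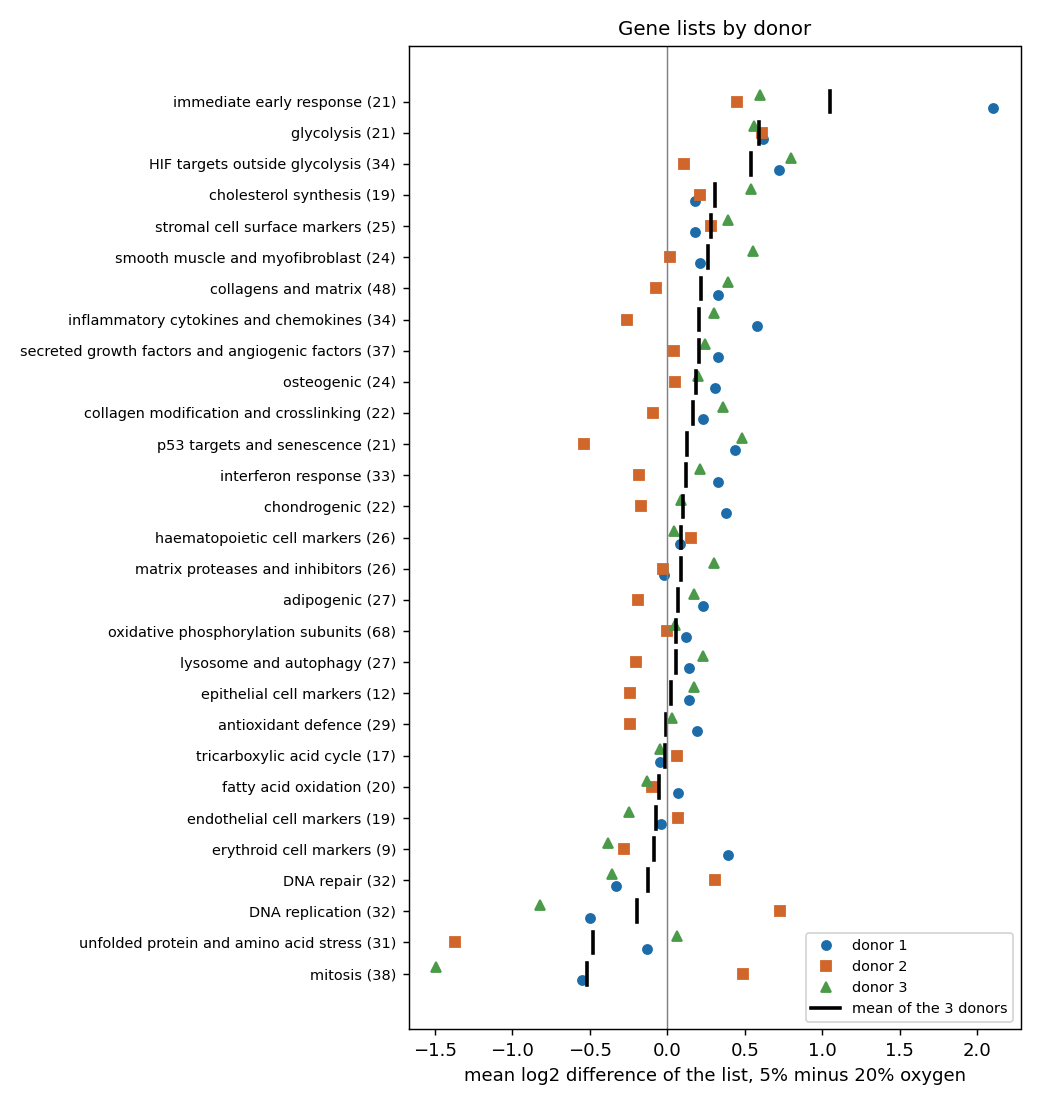
Mean difference in log2(intensity + 16) between 5% and 20% oxygen for each of the 29 gene lists, with the number of measured genes in brackets, 1 point per donor and a bar at the mean of the 3 donors. The glycolysis list lies at 0.62, 0.61 and 0.56 in the 3 donors, while the mitosis list lies at -0.55, 0.49 and -1.49.

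Osteogenic and interferon response genes had means of 0.187 and 0.123 and passed with the donor as a block (adjusted p = 0.0454 and 0.0387) but not without it (adjusted p = 0.105 and 0.158). With the block and an estimated correlation neither passed (adjusted p = 0.735 for both). Without donor 2 or without its 5% oxygen array the interferon list passed at means of 0.272 and 0.271, while it turned to -0.071 without the 5% oxygen array of donor 1. Targets of p53 and senescence genes had a mean of 0.127 and a median of -0.064, so the 2 differed in sign, and the list did not pass (adjusted p = 0.132). Its mean was 0.461 without donor 2, 0.374 without the 20% oxygen array of donor 2 and 0.214 without the 5% oxygen array of donor 2, and each of these passed. It turned to -0.028 without donor 1, -0.051 without donor 3, -0.053 without the 5% oxygen array of donor 1, -0.145 without the 20% oxygen array of donor 3, -0.26 with the 18S covariate and -0.059 without the 5% oxygen arrays of donors 1 and 2, and none of these passed. IGFBP5, a secreted binding protein of insulin-like growth factors in that list, differed by 2.31 ± 0.57 (SE) and passed over the list alone with the donor as a block (adjusted p = 0.0231) but not without it (adjusted p = 0.119). Further probe sets of IGFBP5 differed by as little as 0.55. IGFBP3 of the same list differed by 0.63. The cell cycle inhibitors CDKN1A and CDKN2A differed by 0.40 and -0.13, with CDKN2A probe sets up to 0.22. Antioxidant genes had a mean of -0.006 and a median of 0.048 and did not pass (adjusted p = 0.657). TXNRD1, thioredoxin reductase, differed by -0.92 ± 0.25 (SE), SESN3 by 1.08, SOD2 by 0.22 and TXNIP by -0.05, and none of the 4 passed. Second probe sets of TXNRD1 and TXNIP were higher at 5% oxygen, by 0.29 and up to 0.64. Further probe sets of SESN3 differed by as little as 0.17.

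The remaining metabolic and differentiation lists did not pass. The tricarboxylic acid cycle list had a mean of -0.015 (adjusted p = 0.977) and fatty acid oxidation of -0.052 (adjusted p = 0.957). Matrix proteases and their inhibitors had a mean of 0.086 (adjusted p = 0.158), lysosome and autophagy genes of 0.055 (adjusted p = 0.358), chondrogenic genes of 0.099 (adjusted p = 0.327) and adipogenic genes of 0.068 with a median of -0.01 (adjusted p = 0.372). Without donor 2 the protease and lysosome lists passed at 0.144 and 0.184, and the protease list also passed without the 5% oxygen array of donor 2 (0.167) or the 20% oxygen array of donor 1 (0.22). Both lists turned negative without donor 3 (-0.022 and -0.033) and without its 20% oxygen array (-0.024 and -0.012). Markers of other cell types that marrow cultures could hold did not pass either. Haematopoietic markers had a mean of 0.089 (adjusted p = 0.157), erythroid markers of -0.089 (adjusted p = 0.878), endothelial markers of -0.073 with a median of 0.011 (adjusted p = 0.878) and epithelial markers of 0.023 (adjusted p = 0.942). With fry and the donor as a block the haematopoietic list did pass (adjusted p = 0.0321), against adjusted p = 0.754 without the block. Of the 26 haematopoietic markers measured, 17 were near background. HLA-DRA, a class II antigen presentation gene at 8.37 ± 2.97 intensity units at 5% oxygen and 41.7 ± 11 at 20% (SD, n = 3), passed over that list alone, but not with the donor as a block (adjusted p = 0.0757). It was near background at both oxygen levels, and its second probe set differed by -0.17 against -1.23. Of the 12 epithelial markers, 8 were near background. KRT14, a keratin of that list, was bright and uneven, at 8130 ± 8600 intensity units at 5% oxygen and 3890 ± 3220 at 20% (SD, n = 3). KRT14 differed by 0.99 ± 1.41 (SE), or ± 0.27 with the donor as a block. It was higher in 3 of 3 donors and did not pass over the list alone.

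By the rule for all genes, in lists or not, 8 were taken in each direction. They had the smallest p in the fit with the donor as a block among genes with the same direction in all 3 donors. None passed over all genes. On the higher side, IGFBP1, a binding protein of insulin-like growth factors, differed by 1.43 ± 0.29 (SE) and ZBTB22 by 1.66, both from a mean near background at 20% oxygen, alongside BNIP3, IGFBP5 and MIR210HG. RAB17, a small GTPase, stood at 77.3 ± 14.6 intensity units at 5% oxygen and 7.55 ± 1.36 at 20% (SD, n = 3), a difference of 1.98. ADGRG1 and SOX9-AS1 differed by 1.75 and 1.31. RAB17, ADGRG1 and SOX9-AS1 lay below the 40th percentile of all genes, and second probe sets of ADGRG1, IGFBP1 and SOX9-AS1 were lower at 5% oxygen, by -0.61, -0.10 and -0.27. On the lower side were LYZL1, FGF19, PLCH1-AS1, ANKRD2, TGM3, OR1A2, TEDC2 and LOC101927330, with differences from -1.70 in ANKRD2 to -1.28 in OR1A2. All 8 lay below the 40th percentile, where a mean of 65.9 intensity units in ANKRD2 at 20% oxygen was the brightest.

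Along the first principal component of all genes the 6 arrays did not separate by oxygen level. It held 28.4% of the variance and set the 20% oxygen array of donor 3 (59) apart from the 5% oxygen array of donor 1 (-45.8). The second held 22% and followed the donors, with the arrays of donor 2 at 44.1 and 31.7 and the others from -28.7 to -10.5. The third held 18.4% and did not separate the oxygen levels, and later components were not examined. Across genes, which are not independent replicates, the differences of donors 1 and 2 correlated with r = 0.13, those of donors 1 and 3 with 0.08 and those of donors 2 and 3 with -0.03, and over genes above the 40th percentile the values were 0.29, 0.19 and -0.03. Control probe sets differed between the groups. The 18S ribosomal RNA probe sets stood at 14.19 ± 1.21 log2 units at 5% oxygen and 11.81 ± 0.79 at 20% (SD, n = 3), and the spiked hybridisation controls at 11.21 ± 0.08 and 11.01 ± 0.06. With the 18S signal as a covariate, or without the 5% oxygen arrays of donors 1 and 2, both chosen after seeing the data, 0 glycolysis genes and 0 other targets passed over their lists alone, and 6 of the 29 lists passed in camera against 13. The means of the glycolysis list were then 0.642 and 0.632 and those of the other targets 0.362 and 0.53, and both lists still passed in camera. With the covariate the standard errors of the 2 list means over the arrays were 0.081 and 0.357, against 0.044 and 0.189 without it, so the lost counts do not show that the shift was gone.

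**Figure D3:**
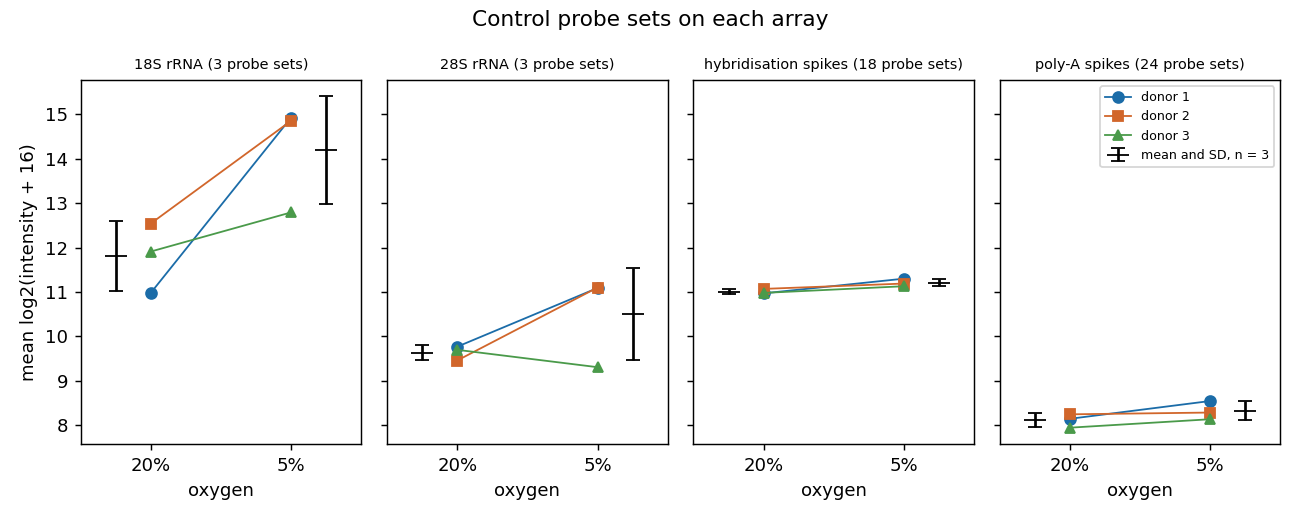
Mean log2(intensity + 16) of 4 families of control probe sets on each array at 20% and 5% oxygen, with a line joining the arrays of a donor and the mean and SD of each group (n = 3) beside them. The 18S ribosomal RNA signal is 3.94, 2.30 and 0.88 higher at 5% oxygen in donors 1, 2 and 3, and the hybridisation spikes are 0.20 higher on average.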

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

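The tests of scaling, brightness, RNA degradation and the 18S ribosomal RNA signal were chosen only after the results were seen. Leaving out each array was fixed in advance, but its use to explain the mitosis list was chosen after. Signals outside the gene comparison drew attention because every array at 5% oxygen lay above every array at 20% oxygen in the mean of a control family. By chance, 10% of the splits of 3 against 3 give a complete separation in either direction. Several control families were scanned, with no allowance for that. The 18S ribosomal RNA probe sets were 2.38 log2 units brighter at 5% oxygen, and the spiked hybridisation controls were 0.20 brighter. For 18S the order held for the mean of its 3 probe sets, but not for its 3' set. That set read 3051 units on the 5% oxygen array of donor 3 and 3991 on the 20% oxygen array of donor 2. The control probe set for Alu repeats had the same order, at 40022 to 40230 intensity units against 33756 to 38351. So did the 99th percentile of all probe sets, at 15151 to 15469 against 13900 to 14703. The brightest probe set of each array also did, at 44322 to 45255 against 40335 to 41818. The poly-A spikes did not have that order, but were 0.21 brighter on average, by 0.40, 0.03 and 0.19 in donors 1, 2 and 3. Groups of 3 arrays are too small for a test of outlying arrays.

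The 18S ribosomal RNA difference was 3.94, 2.30 and 0.88 in donors 1, 2 and 3, while the mean of the 3 28S probe sets differed by 1.32, 1.64 and -0.39. Their 3' set read only 18 to 85 intensity units. The 5' set was higher at 5% oxygen in every donor, at 32046, 27528 and 4139 units against 2890, 4080 and 2697. The middle set was higher in donors 1 and 2 and lower in donor 3, at 1765 against 2334. A scaling that lifts all bright probe sets is argued against, since the hybridisation spikes were 0.20 brighter with an SD of at most 0.08, far below 2.38, and the 10% of genes with the highest mean had a median difference of 0.039. More degraded RNA at 5% oxygen was set against the ratio of 3' to 5' probe sets of ACTB, which was higher at 5% oxygen in 2 of 3 donors, with log2 differences of 0.51, 0.10 and -0.34, while the GAPDH ratio differed by 0.08, -0.04 and -0.01. That explanation stays open, because the ACTB differences follow the order of the 18S differences but turn negative in donor 3, where 18S was still higher, the GAPDH differences are small, and 3 donors are few. Carry-over of ribosomal RNA during amplification and a biological difference between oxygen levels were not tested.

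The higher glycolysis list and the higher list of other hypoxia-inducible factor targets were set against the same technical measures. A lift of bright probe sets is argued against for both lists, whose medians lay at the percentile of 100 among matched random lists. With the 18S signal as a covariate at the level of arrays, the glycolysis difference was 0.642 with a standard error of 0.081, against 0.593 and 0.044 without it, which argues against that signal as the whole source. The 18S signal correlated with the oxygen group with r = 0.82 over the 6 arrays, so that fit separates them poorly. That fit was also unpaired, and with the 18S differences within donors as the covariate the glycolysis difference was 0.547 with a standard error of 0.024. The fit within donors is a line through 3 points, extended below the smallest 18S difference of 0.88, so its standard error is itself uncertain. For the other targets the difference was 0.362 with a standard error of 0.357, against 0.543 and 0.189, and within donors it was 0.58 with a standard error of 0.661. Their list differences of 0.72, 0.11 and 0.80 in donors 1, 2 and 3 did not follow the 18S differences, and their mean was 0.53 without the 5% oxygen arrays of donors 1 and 2. RNA differences that go with the 18S signal stay open for them, because 3 donors leave wide errors and 1 array at 5% oxygen is left without those 2. For glycolysis a response to oxygen remains a hypothesis, and it was found and tested on the same 6 arrays.

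The lower mitosis list had a mean of -0.516, with all 38 genes lower on average but the opposite direction in donor 2. The 20% oxygen array of donor 3 may account for much of that mean, which was -0.081 without that array. Without donor 2 the mean was -1.018, and the list differences of -0.55 and 0.49 in donors 1 and 2 do not involve that array. On that array the list mean was 12.44 log2 units, against 10.81 to 11.41 on the other 5 arrays. Whether the donors' cultures differed in growth at collection was not tested, and an effect of oxygen on cycling in some donors stays open.

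With 10 splits of the 6 arrays into groups of 3, no share below 0.1 can be reached, so the splits are too few to decide. The real split gave 0 genes past the threshold, as did the 10 splits counting the real one, and the highest of the others was 0. At an unadjusted p under 0.05 it gave 1193 genes and the others 631 to 1524, and those of the others that part all 3 donor pairs gave 631 to 960. It gave 13 lists, a number reached by 2 of the 10 splits counting the real one, and the highest other was 13. It gave 10 glycolysis genes over the list alone, where the highest other split gave 0, and 7 other targets, where the highest other gave 0, each reached by 1 of the 10 splits. Of the splits, 4 part all 3 donor pairs, and the other split with 13 lists is one of them, with the 2 arrays of donor 2 exchanged between the groups. In the fit with the donor as a block, run on these 4 after seeing the data, the real split gave 1379 genes at an unadjusted p under 0.05, 14 lists, 8 glycolysis genes and 7 other targets, where the highest of the 3 others were 1072, 16, 0 and 1. No share below 0.25 can be reached there.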

How the results depend on the processing

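The 18S covariate, the removal of the 5% oxygen arrays of donors 1 and 2, the pseudocounts for results other than the count of genes, and all counts over a list alone were chosen only after the data were seen. The count of 0 genes past the threshold was obtained with every alternative run, including each array left out (0 to 0), with a smallest adjusted p from 0.0917 (pseudocount 1) to 0.999 (without donor 1). At an unadjusted p under 0.05 limma gave 1193 genes, and 1379 with the donor as a block. With the donor as a replicate block the counts were 0 genes, 14 lists against 13, 7 other targets against 7 and 8 glycolysis genes against 10, and with a random replicate block 0 genes, 7 and 11. Changes of single calls in the paired fit are given beside the results. In the form of fry that lets genes of a list move either way, not used in the report, the other hypoxia-inducible factor targets were lost with the block (adjusted p = 0.00335 without it and 0.0741 with it) and antioxidant defence was gained (0.789 and 0.0157). The random block and the robust prior were not run for the lists. The glycolysis mean ran from 0.489 to 0.642 and that of the other hypoxia-inducible factor targets from 0.362 to 0.76 over the 20 settings tested with camera's preset correlation, and both passed in all 20, as did the stromal surface markers. With arrays or donors left out the ranges were 0.568 to 0.631 and 0.409 to 0.76. With an estimated correlation 0 lists passed, with the means of 0.593 and 0.543 no longer past, and with fry 2 passed and the mean of 0.543 was no longer past. The 13 lists became 7 with specific probe sets preferred, 6 without the 5% oxygen arrays of donors 1 and 2, 6 with the 18S covariate, and 5 to 18 with arrays or donors left out. The 7 other targets became 13 with an intensity trend, 9 with dim genes left out, 5 with the mean of all probe sets or with specific ones preferred, 0 with a pseudocount of 1, 12 with a pseudocount of 64, 0 without the 5% oxygen arrays of donors 1 and 2, 0 with the 18S covariate, and 0 to 8 with arrays or donors left out. The 10 glycolysis genes became 15 with an intensity trend, 15 with a pseudocount of 64, 12 with dim genes left out, 11 with each array centred, 9 with specific probe sets preferred, 8 with quantile normalization, 8 with a pseudocount of 1, 5 with the mean of all probe sets, 0 without those arrays, 0 with the covariate, and 0 to 9 with arrays or donors left out. Fewer arrays may explain part of the losses when arrays are left out, and the cause was not tested.

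None of the 97 named genes run in the alternatives passed over all genes in any of the 22 settings that gave them a value, and 82 kept their direction throughout. KRT14 was not run in them. The sign turned for the following lists and genes, and the cause was not tested. With the mean of all probe sets these were fatty acid oxidation (0.002), antioxidant defence (0.016), endothelial markers (0.027), EPAS1 (0.28), VHL (0.16), TXNIP (0.24), COX4I1 (-0.11) and CDKN2A (0.08). With specific probe sets preferred these were oxidative phosphorylation (-0.021), the tricarboxylic acid cycle (0.029), P4HA1 (-0.21), HIF3A (-0.20), VHL (0.46), COX4I1 (-0.63), CDKN2A (0.22) and AKR1C2 (-0.37). With a pseudocount of 1 these were antioxidant defence (0.012) and epithelial markers (-0.072). Without the 5% oxygen arrays of donors 1 and 2 these were the tricarboxylic acid cycle (0.02), fatty acid oxidation (0.09), p53 targets (-0.059), antioxidant defence (0.047), adipogenic (-0.068), chondrogenic (-0.247), immediate early (-0.165) and epithelial lists (-0.107), TXNIP (0.39), ATF3 (-0.99), FOS (-0.83) and COX4I2 (0.32). With the 18S covariate these were the tricarboxylic acid cycle (0.052), DNA replication (0.113), DNA repair (0.026), p53 targets (-0.26), adipogenic (-0.15), chondrogenic (-0.34), smooth muscle (-0.161), inflammatory (-0.191), immediate early (-0.67), haematopoietic (-0.01) and epithelial lists (-0.152), TXNIP (0.41), ATF3 (-2.04), FOS (-2.09), COX4I2 (0.02), CDKN1A (-0.18) and SOD2 (-0.44). With arrays or donors left out the sign turned within the ranges for DNA replication (-0.66 to 0.117), adipogenic (-0.049 to 0.199), antioxidant defence (-0.104 to 0.11), chondrogenic (-0.1 to 0.273), endothelial (-0.22 to 0.047), epithelial (-0.113 to 0.153), erythroid (-0.329 to 0.093), fatty acid oxidation (-0.173 to 0.056), interferon (-0.071 to 0.272), lysosome (-0.033 to 0.184), matrix protease (-0.024 to 0.22), p53 target (-0.145 to 0.461) and tricarboxylic acid cycle lists (-0.05 to 0.018). The same held for CDKN2A (-0.42 to 0.07), COX4I2 (-0.43 to 0.12), EPAS1 (-0.38 to 0.31), NDRG1 (-0.18 to 0.41), SOD2 (-0.24 to 0.49), TRIB3 (-2.60 to 0.06), TXNIP (-0.28 to 0.12) and VHL (-0.27 to 0.02). Signal over background limits the 40% of genes below 57.7 intensity units, where all 8 named lower genes lie.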

Other observations

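All genes and counts here, apart from those already named by rule, were chosen only after their values were seen. Among the 11844 genes above the 40th percentile of expression, 18 were more than 1 log2 unit higher at 5% oxygen in all 3 donors and 1, the potassium channel gene KCNG1, was more than 1 lower. Over all 19740 genes the counts were 28 and 13, so the imbalance was smaller with dim genes included. The other 6 combinations of directions over the donors held 0 to 8 genes. Besides AK4, BNIP3, PDK1, MIR210HG, FOS, IGFBP1, IGFBP5, ZBTB22 and COL14A1, the 18 were AKR1C1, AKR1C2, AKR1C3, C11orf96, DUSP4, GAP43, GEM, MALL and SCUBE3. SCUBE3, a secreted signalling protein, stood at 22000 ± 2400 intensity units at 5% oxygen and 8480 ± 1860 at 20% (SD, n = 3), with differences of 1.21, 1.14 and 1.82 in donors 1, 2 and 3. GAP43, a neuronal growth protein, differed by 2.25 and DUSP4, a kinase phosphatase, by 1.90 from a level near background at 20% oxygen. AKR1C1, AKR1C2 and AKR1C3, neighbouring aldo-keto reductase genes of steroid metabolism, differed by 2.12, 2.12 and 2.54. These 3 genes are related in sequence, so some of their probe sets may read more than 1 of them. Further probe sets of AKR1C1 and AKR1C2 differed by -0.06 and -0.37. None of the 18 passed over all genes in limma.

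The list of the unfolded protein response and amino acid stress was highest on the 20% oxygen array of donor 2, where its mean was 12.33 log2 units against 10.88 to 11.17 on the other 5. The 4 members named next were picked for their size, and other members of the list did not follow them, some being higher at 5% oxygen in donor 2. ASNS, asparagine synthetase, read 12800 intensity units there and 804 to 1507 on the others. It differed by -3.97 in donor 2 against -0.29 and -0.28 in donors 1 and 3, and TRIB3, a stress-induced pseudokinase, by -4.54 against -0.35 and -0.04. SLC7A5, an amino acid transporter, differed by -3.11 in donor 2 and -0.79 and -0.16 in the others. PSAT1, an enzyme of serine synthesis, differed by -3.71 in donor 2, 0.43 in donor 1 and -1.78 in donor 3. A single culture per donor and oxygen level gives these differences no replicate.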
